A study of Mus musculus with 2 samples.

How the data were processed

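Brown adipose tissue of C57BL/6 mice, a standard inbred laboratory strain, was profiled by single-nucleus RNA sequencing. Per the labels, 1 library came from mice kept at thermoneutrality, the ambient temperature at which no extra heat production is needed (TN). The other came from mice that had gone through a transient acute cold exposure 4 days before collection (1cyc). Per the series' design text, nuclei of 5 mice were pooled for each library and the mouse of each nucleus is not recorded. Nuclei were sorted as DAPI-positive, which selects particles with DNA, and were loaded on the 10X Genomics droplet platform, per the labels. Sequencing was on a NextSeq 550.

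The deposited values were raw UMI counts per gene and barcode, with no normalization. UMIs are molecular identifiers that count each captured molecule once. The reads were aligned to mm10 and counted with Cell Ranger 3, per the submitters' processing notes; the matrix header gives version 3.1.0, per the file headers. The annotation version and whether intronic reads were counted are not given in the sources used here. The barcodes were already filtered, per the design text, and the lowest deposited barcode held 500 UMIs in TN and 262 in 1cyc, so the lower limit differed between the libraries. Gene positions were taken from GENCODE M21 on the mm10 assembly, which held 30934 of the 31053 gene identifiers (99.6%) and may be another annotation version than the authors used.

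Nuclei with at least 200 detected genes and under 5% mitochondrially encoded UMIs were kept. This left 1303 of 2551 TN barcodes (51.1%) and 1065 of 4321 1cyc barcodes (24.6%). Scrublet, as implemented in scanpy 1.11.5, was run on each library and its doublet calls were removed, 10 in TN and 9 in 1cyc. The remaining 1293 and 1056 nuclei were normalised to 10000 UMIs, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered together with the Leiden method at resolution 0.6, with no integration of the libraries. Clusters were named from 16 lists of cell type markers. A name required at least 3 markers at 1.5-fold or more over the mean of all clusters, no more markers of another class than of its own among the 10 leading genes, and fewer than 5 mitochondrially encoded genes among these 10. These naming thresholds, and the second clustering of 1 non-adipocyte cluster that held markers of several classes, were set after the first clustering was seen. Unnamed clusters held 1.62% of TN and 0.189% of 1cyc nuclei. One of them was led by haemoglobin genes and the other by Lyz2 and ribosomal protein genes. In 3 alternative settings an unnamed cluster scored best as adipocyte, and all adipocyte results were computed again with it counted.

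UMIs were summed over the adipocyte nuclei of each library, 1029054 in TN and 960109 in 1cyc, and scaled to CPM, the counts per 1e6 UMIs of the sum. Genes with at least 100 UMIs over both sums were compared, which held for 3417 of 17295 genes with a UMI. Because each condition is 1 pooled library, no test between conditions was possible, no p-value was computed and genes were counted by the size of the CPM ratio alone. Each CPM has an exact Poisson interval, each ratio an exact conditional binomial interval and each share of nuclei an exact Clopper-Pearson interval, all at 95%. These intervals cover counting error only. They hold nothing of the spread between mice, dissections or library preparations. A ratio against 0 UMIs was set against a floor of 3 counts.

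Named genes were the 12 highest and the 12 lowest by the interval bound of the CPM ratio nearest to 1. Mitochondrially encoded, ribosomal protein and haemoglobin genes and unnamed gene models were counted but not named by rank. In any other class with at least 100 nuclei per library, the 3 highest and 3 lowest genes with at least 50 UMIs were named. The 17 lists of metabolic and signalling genes, 3 technical lists and 16 marker lists, the rule for named genes, the filters and the alternatives, except those named as added later, were chosen before the data were examined. The median log2 ratio of each list with at least 3 measured members was placed as a percentile among 10000 random lists of the same size matched on mean CPM. The interval of a list's median came from 2000 Poisson draws of its counts.

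For values per nucleus, each adipocyte nucleus was thinned to 500 UMIs and shallower nuclei were left out. A nucleus was called high when it held more fatty acid synthesis UMIs than the 90th percentile of TN adipocyte nuclei. Co-variation was the correlation across nuclei between UMIs of alternate genes of that list, placed among 1000 matched random lists. It was planned with 1 thinning and is given so. A median over 20 thinnings was added after the value was seen to move between draws. Adipocyte nuclei were also clustered again at resolution 0.4 without the fatty acid synthesis list. A further clustering, added after the data were seen, also left out the white adipocyte list and genes with at least 30 UMIs that lay 1.5-fold or more apart.

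The calculations were tested on simulated counts with the adipocyte means and totals of this comparison and 200 changed genes. Gene sums were drawn as independent Poisson counts, the model the intervals assume, with no spread between nuclei. The rates for genes and lists thus check the calculation and are not error rates for these data. Intervals covered the true ratio in 95.5% of 3285 genes, and 1 of 3104 unchanged genes appeared 2-fold apart. Of the changed genes, 1.56% of 64 with a 1.5-fold change, 90% of 60 with a 2.5-fold change and 100% of 57 with a 4-fold change appeared at least 2-fold apart. Of 200 unchanged lists, 6% fell beyond the 2.5 or 97.5 percentile, and 100% of 50 lists raised 1.5-fold lay above the 97.5 percentile. For co-variation, simulated nuclei without any difference between them gave a median correlation of −0.00512 in TN and −0.00157 in 1cyc over 20 simulations. With the list 3-fold higher in 10% of nuclei the values were 0.235 and 0.306.

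Alternatives covered the filters on nuclei and genes, doublet removal, clustering resolution, scaling within library, scaling of the sums (TMM in edgeR 4.0.16, totals without mitochondrially encoded genes, median ratio), equal weight per nucleus, thinning, and the settings of the values per nucleus. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9 and R 4.3.3 were used.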

Results

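Brown adipose tissue burns fuel to produce heat and is activated by cold. The series title names lipogenic brown adipocytes and thermogenic memory, and the comparison asks how nuclei of this tissue differed between mice kept at thermoneutrality (TN) and mice sampled 4 days after a transient acute cold exposure (1cyc). Each condition was 1 library of nuclei pooled from 5 mice, so there was no replicate check of any difference, and condition and library cannot be told apart. The TN library held 2551 barcodes with 2745808 UMIs and a median of 800 UMIs per barcode. The 1cyc library held 4321 barcodes with 2469900 UMIs and a median of 378. The median share of mitochondrially encoded UMIs was 4.76% in TN and 22.1% in 1cyc, over barcodes deposited from 500 UMIs in TN and from 262 in 1cyc. After filtering, 1293 TN nuclei with a median of 886 UMIs and 1056 1cyc nuclei with a median of 904 UMIs remained. Values in parentheses after a share, level or ratio are 95% intervals for counting error only. Transcripts of Y-linked genes such as Uty were present in both libraries (521 CPM in TN and 410 CPM in 1cyc adipocyte nuclei).

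Adipocytes made up most nuclei in both libraries, 1023 of 1293 in TN (79.1%, 76.8 to 81.3) and 925 of 1056 in 1cyc (87.6%, 85.5 to 89.5). Fibroblasts or progenitors were 10.5% (8.90 to 12.3) in TN and 7.01% (5.54 to 8.72) in 1cyc, and endothelial nuclei were 3.17% (2.28 to 4.28) and 2.08% (1.31 to 3.14). Skeletal muscle nuclei were 2.24% and 1.04%, macrophages or monocytes 1.47% and 1.04%, pericytes 1.31% and 0.852%, and smooth muscle nuclei 0.541% and 0.189%. The mitochondrial filter and the naming of clusters can set these shares. With a limit of 2% the adipocyte share was 57.9% in TN and 57.0% in 1cyc, and with no filter it was 68.6% and 31.0%. Each of these settings left unnamed a cluster that scored best as adipocyte. At the 2% limit it held 91 TN (25.6%) and 174 1cyc nuclei (35.8%). F13a1, a macrophage marker, led it, and its 10 leading genes also included Dock2, Mctp1, Decr1, Ppp1r3b, Fabp3 and Fras1. None of these 10 was on the adipocyte list, but 12 adipocyte markers were at 1.5-fold or more over the mean of all clusters. Its identity is therefore unsure. With no filter it was led by mitochondrially encoded genes, which made up 7 of its 10 leading genes, and held 41 TN (1.61%) and 2657 1cyc barcodes (61.6%). Its other leading genes were Myo3a, Pnpla3 and Tkt, and the last 2 are among the higher genes named below. With that cluster counted, a choice made after seeing the data, the shares were 83.4% and 92.8% at the 2% limit and 70.2% and 92.6% with no filter, so the opposite direction without a filter rests on the naming. Adipocytes fell into 3 clusters that the libraries filled unequally. A cluster led by Rnf182, Erbb4 and Ppara held 649 TN and 268 1cyc nuclei, one led by Cib4, Ucp1 and Slc36a2 held 274 and 627, and one led by Nnat, Slc7a10 and Adrb3 held 100 and 30.

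Among 3417 genes measured in adipocyte nuclei, 33 were at least 2-fold higher and 42 at least 2-fold lower in the 1cyc library, and 89.3% lay within 1.5-fold. Pnpla3, which encodes a lipid droplet protein, stood at 369 CPM in 1cyc against 110 CPM in TN, a ratio of 3.36 (2.71 to 4.19). Plin2, a coat protein of lipid droplets, had a ratio of 2.68 (2.17 to 3.31), and Acot11, an acyl-CoA thioesterase, 3.30 (2.53 to 4.34). Acly, which makes cytosolic acetyl-CoA from citrate, rested on 130 and 323 UMIs with a ratio of 2.66 (2.17 to 3.29). Scd1, the stearoyl-CoA desaturase, had a ratio of 2.78 (2.14 to 3.65). Tkt, transketolase of the pentose phosphate pathway, had 2.41 (2.13 to 2.73), Ldha, a lactate dehydrogenase subunit, 3.06 (2.18 to 4.36), and Ppp1r3b, which targets a phosphatase to glycogen, 2.90 (2.25 to 3.77). The kinase gene Pim1 had a ratio of 3.45 (2.65 to 4.54). Flcn, which encodes folliculin, had 2.63 (1.88 to 3.71), Abhd15 2.32 (1.84 to 2.94) and Gucd1 2.28 (1.78 to 2.93). Plin2 had a higher level in TN non-adipocyte (152 CPM) than in TN adipocyte nuclei (123 CPM). In non-adipocyte nuclei, most of the named higher genes also had a higher CPM in 1cyc than in TN, on few UMIs. Scd1 had 14 TN and 15 1cyc UMIs there (30.5 and 109 CPM), while Acly was lower in 1cyc (41.4 and 29.0 CPM). In mm10 coordinates, Pnpla3 (ENSMUSG00000041653) lies on chromosome 15 from 84167837 to 84187236, Acly (ENSMUSG00000020917) on chromosome 11 from 100476353 to 100528000 and Scd1 (ENSMUSG00000037071) on chromosome 19 from 44394455 to 44407879.

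Among the lower genes in 1cyc adipocyte nuclei, Nnat, the imprinted gene of neuronatin, stood at 1031 CPM in TN and 316 CPM in 1cyc, a ratio of 0.306 (0.269 to 0.348). Slc7a10, an amino acid transporter gene, had a ratio of 0.266 (0.176 to 0.392), Tshr, the thyrotropin receptor, 0.345 (0.261 to 0.451) and Igf1 0.241 (0.140 to 0.395). Steap4, a metalloreductase gene also on the pericyte marker list, had 0.194 (0.122 to 0.295), and Aldh1a1, a retinaldehyde dehydrogenase gene, 0.225 (0.146 to 0.335). Dock11 had a ratio of 0.190 (0.106 to 0.320), Cyp2e1 0.237 (0.140 to 0.383), Abcd2, a peroxisomal transporter gene, 0.304 (0.232 to 0.395), Eepd1 0.325 (0.259 to 0.406), Ccdc80 0.298 (0.209 to 0.417) and Slit3 0.367 (0.314 to 0.428). Of these, Slit3 (1304 CPM), Aldh1a1 (353 CPM) and Dock11 (157 CPM) had higher levels in TN non-adipocyte than in TN adipocyte nuclei. Fibroblast or progenitor markers were also lower within 1cyc adipocyte nuclei, at 380 CPM in TN and 208 CPM in 1cyc. Nnat (ENSMUSG00000067786) lies on chromosome 2 from 157560078 to 157562522, and Slc7a10 (ENSMUSG00000030495) on chromosome 7 from 35186385 to 35201114. With TMM scaling, 21 genes were at least 2-fold higher and 51 at least 2-fold lower.

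**Figure D1:**
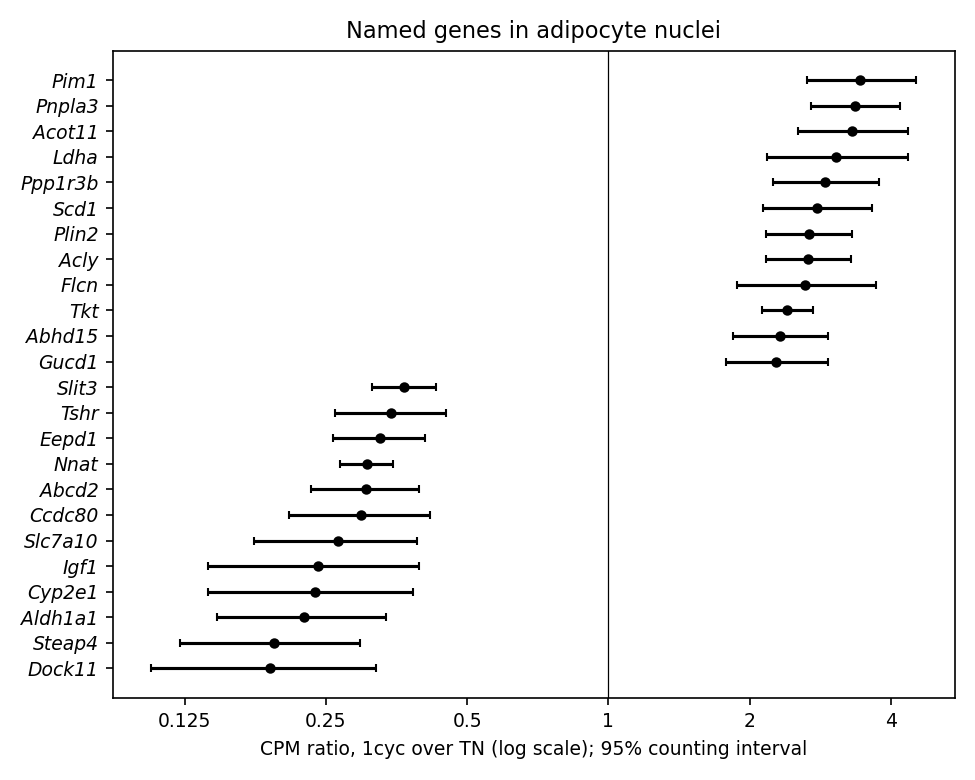
CPM ratio of 1cyc over TN for the 24 named genes in adipocyte nuclei, on a log scale, with 95% intervals for counting error. Pim1 is highest at 3.45 and Dock11 lowest at 0.190. Every interval excludes 1, which follows from picking the genes by the interval bound nearest to 1.

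The fatty acid synthesis list was higher in the 1cyc adipocyte nuclei for 9 of its 10 measured members. Its median log2 ratio was 0.61 (0.49 to 0.70), above all of the matched random lists (100th percentile). It was 0.32 (0.22 to 0.42) with no filter on nuclei and the cluster led by mitochondrially encoded genes counted. In that setting the totals hold a larger share of mitochondrially encoded UMIs in 1cyc, which lowers the 1cyc CPM of all other genes. Besides Acly and Scd1, which were at least 2-fold higher, Acaca, the gene of acetyl-CoA carboxylase, stood at 1490 CPM in TN and 2341 CPM in 1cyc (ratio 1.57, 1.47 to 1.68). Elovl6, a fatty acid elongase gene, had a ratio of 1.57 (1.38 to 1.79), Acss2 1.79 (1.51 to 2.13) and Mlxipl, which encodes the glucose-responsive factor ChREBP, 1.36 (1.22 to 1.51). Srebf1 had 1.12 (0.786 to 1.60) and Me1, the exception, 0.893 (0.613 to 1.30). Fasn, the fatty acid synthase gene, fell below the minimum of 100 UMIs, with 15 UMIs in TN and 83 in 1cyc (ratio 5.93, 3.40 to 11.1). Summed over the 16 genes of the list, adipocyte nuclei held 4994 CPM (4858 to 5132) in TN and 7347 CPM (7177 to 7521) in 1cyc. Non-adipocyte nuclei, which should hold little of it, had 891 CPM (806 to 981) and 1677 CPM (1468 to 1908). Blood genes took 163056 CPM of the TN non-adipocyte sum and 211 CPM of the 1cyc one, which lowers all other TN values in that sum.

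The thermogenesis list was also higher in 1cyc, for 11 of 13 measured members, with a median log2 ratio of 0.39 (0.31 to 0.47) at percentile 99.97. Ucp1, the uncoupling protein that releases heat, stood at 142 CPM in TN and 274 CPM in 1cyc (ratio 1.93, 1.57 to 2.38). The potassium channel gene Kcnk3 had a ratio of 1.68 (1.42 to 1.99), the transcriptional regulator gene Prdm16 1.45 (1.25 to 1.67) and the coactivator gene Ppargc1a 1.36 (1.14 to 1.62). Esrrg had 0.984 (0.936 to 1.04) and Adrb3, the beta-3 adrenergic receptor, 0.841 (0.632 to 1.12). None of the 13 measured members was 2-fold apart, and with no filter on nuclei and the cluster led by mitochondrially encoded genes counted the median was 0.14 (0.05 to 0.24). Non-adipocyte nuclei had 2935 CPM of the list in TN and 3761 CPM in 1cyc, against 15124 CPM and 18396 CPM in adipocyte nuclei. Clustered without the fatty acid synthesis list, TN nuclei of the smaller adipocyte subcluster had 2802 CPM of thermogenesis transcripts and those of the larger 17271 CPM. The smaller held 14.8% of TN and 4.46% of 1cyc adipocyte UMIs, so its lower share can give part of the rise. Within the larger the median was 0.29 (0.19 to 0.36, percentile 99.8). Its summed ratio was 1.10 (1.08 to 1.13), against 1.22 (1.19 to 1.24) over all adipocyte nuclei.

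Lists of fuel uptake and use were higher in 1cyc as well. Glucose uptake and glycolysis had a median log2 ratio of 0.46 (0.29 to 0.73, percentile 99.9) with 10 of 11 members higher, among them Pkm, a pyruvate kinase gene, at 2.14 (1.69 to 2.73) and Hk2, a hexokinase gene, at 1.92 (1.54 to 2.39). Fatty acid uptake and triglyceride synthesis had 0.39 (0.24 to 0.47, percentile 99.99) with 11 of 14 higher. In that list Agpat2 had a ratio of 2.57 (1.69 to 3.98), Gpd1, the glycerol-3-phosphate dehydrogenase gene, 1.99 (1.75 to 2.27), and the fatty acid transporter gene Slc27a1 0.621 (0.519 to 0.741). Fatty acid oxidation had 0.23 (0.15 to 0.32, percentile 99.1) with 12 of 15 higher, led by Slc25a20, the mitochondrial carnitine carrier gene, at 1.66 (1.35 to 2.06) and Acaa2 at 1.55 (1.34 to 1.79). Glycogen metabolism had 0.20 (0.10 to 0.39, percentile 93.9) with 8 of 8 higher, and lipolysis 0.15 (0.09 to 0.32, percentile 90.4) with 9 of 11 higher; these medians lay inside the middle 95% of random lists. Within the larger subcluster of adipocyte nuclei clustered without the fatty acid synthesis list, lipolysis had 0.29 (0.20 to 0.39, percentile 99.2) and glycogen metabolism 0.26 (0.08 to 0.42, percentile 97.9), above the middle 95% of random lists. There glucose uptake and glycolysis had 0.36 (0.25 to 0.65, percentile 99.6) and fatty acid uptake and triglyceride synthesis 0.38 (0.29 to 0.49, 100th percentile), while fatty acid oxidation had 0.18 (0.05 to 0.25, percentile 97.47) and lay inside the middle 95%. In the smaller subcluster 0 of 3 fatty acid oxidation members were higher, with a median of −0.40 (−0.97 to −0.15, percentile 11.6) inside the middle 95% and a summed ratio of 0.838 (0.694 to 1.01). Fatty acid uptake and triglyceride synthesis had 0.05 (−0.13 to 0.34) and lipolysis 0.11 (−0.11 to 0.28) in that subcluster. With no filter on nuclei and the cluster led by mitochondrially encoded genes counted, uptake and triglyceride synthesis had 0.09 (−0.02 to 0.18), oxidation 0.07 (−0.03 to 0.14) and glycolysis 0.30 (0.18 to 0.52) over all adipocyte nuclei. Over all adipocyte nuclei lipolysis turned to −0.0204 with a mitochondrial limit of 2%, and to 0.09 (−0.06 to 0.20) there with the unnamed cluster counted.

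**Figure D2:**
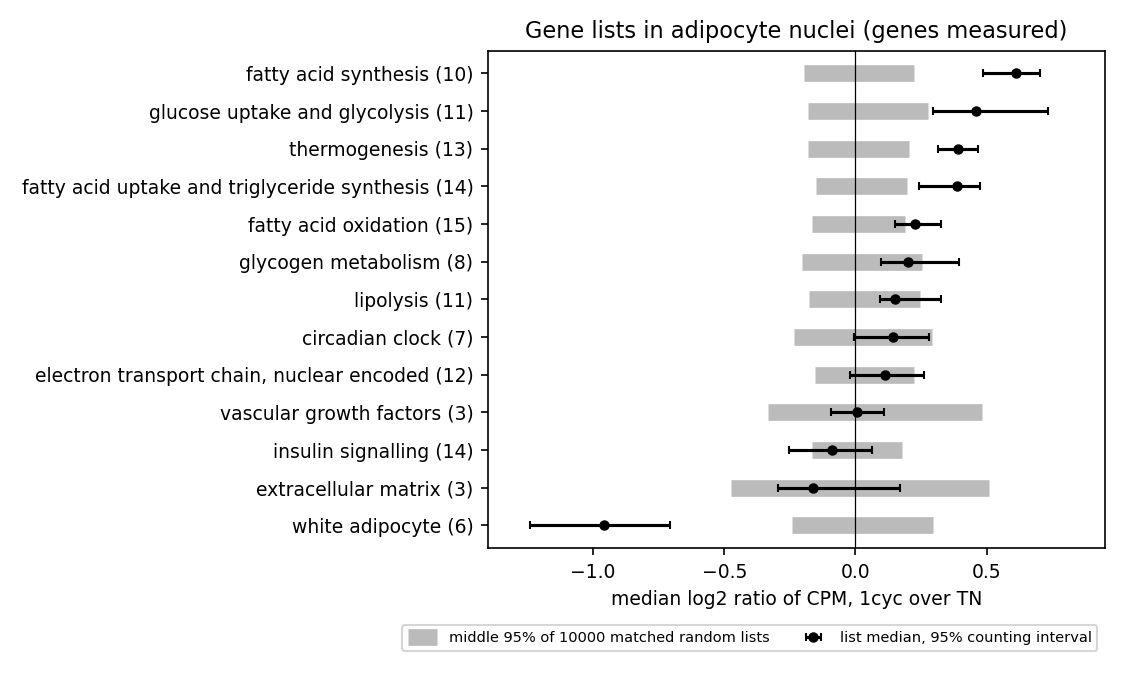
Median log2 ratio of CPM, 1cyc over TN, for the lists of metabolic and signalling genes with at least 3 measured members in adipocyte nuclei (number measured in parentheses). Points with bars are medians with 95% intervals for counting error and grey bars the middle 95% of 10000 matched random lists. Of the lists drawn, fatty acid synthesis is highest at 0.61 and the white adipocyte list lowest at −0.96.

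The white adipocyte list was lower in 1cyc for 6 of 6 measured members, with a median log2 ratio of −0.96 (−1.24 to −0.71) below all matched random lists (0th percentile). Besides Nnat and Slc7a10, the adipsin gene Cfd had a ratio of 0.446 (0.310 to 0.632) and the natriuretic peptide receptor gene Npr3 0.594 (0.504 to 0.699). Lep, the leptin gene, rested on 66 and 29 UMIs (ratio 0.471, 0.293 to 0.739). Clustered without the fatty acid synthesis list, adipocyte nuclei fell into a larger and a smaller subcluster. The smaller one was led by Slc7a10, Nnat, Dock11 and Aldh1a1, genes that also differed between the libraries. Clustered also without the white list and every gene at least 1.5-fold apart, a choice made after seeing the data, it held 85 of 1023 TN nuclei (8.31%, 6.69 to 10.2) and 30 of 925 1cyc nuclei (3.24%, 2.20 to 4.60). In that clustering the white list stood at 9635 CPM in TN and 8494 CPM in 1cyc within the smaller subcluster (ratio 0.882, 0.782 to 0.992), and at 925 CPM and 592 CPM within the larger one (ratio 0.640, 0.573 to 0.714). Nnat held 241 of the 824 TN and 66 of the 543 1cyc UMIs of the list in the larger subcluster, and without it the ratio was 0.794 (0.702 to 0.898). There 3 of 5 measured members were lower and 2 higher, with a median log2 ratio of −0.48 (−0.74 to −0.18), and Slc7a10, a leading gene of the smaller subcluster, held 21 TN and 2 1cyc UMIs. In the clustering without the fatty acid synthesis list alone, which used genes of the white list, the ratios were 1.00 (0.895 to 1.12) and 0.654 (0.582 to 0.734). In the clustering without genes at least 1.5-fold apart, 39 of the 42 genes at least 2-fold lower in 1cyc were at least 2-fold higher in the smaller than in the larger subcluster of TN, against 277 of all 3417 genes. Within its larger subcluster alone, 11 genes were at least 2-fold lower and 25 at least 2-fold higher in 1cyc, and 22 of the 42 genes were measured.

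In the clustering without the fatty acid synthesis list alone, fatty acid synthesis transcripts were higher in 1cyc in both subclusters. They stood at 5310 CPM and 7496 CPM in the larger (ratio 1.41, 1.36 to 1.47) and 3182 CPM and 4154 CPM in the smaller (ratio 1.31, 1.09 to 1.55). In the smaller, the 3 measured members had a median log2 ratio of 0.41 (−0.001 to 0.92, percentile 94.5), inside the middle 95% of random lists. Non-adipocyte nuclei had 891 CPM and 1677 CPM of the list. The rise in the smaller subcluster thus cannot be told apart from a rise in free RNA. Thermogenesis transcripts were 17271 CPM and 19078 CPM in the larger subcluster, and 2802 CPM and 3804 CPM in the smaller one. Non-adipocyte nuclei had 2935 CPM and 3761 CPM of them, close to the smaller subcluster. In the clustering also without genes at least 1.5-fold apart, fatty acid synthesis transcripts were 5310 CPM and 7481 CPM in the larger and 2956 CPM and 4437 CPM in the smaller. Thermogenesis transcripts were 17026 CPM and 19017 CPM, and 2847 CPM and 4864 CPM, there.

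**Figure D3:**
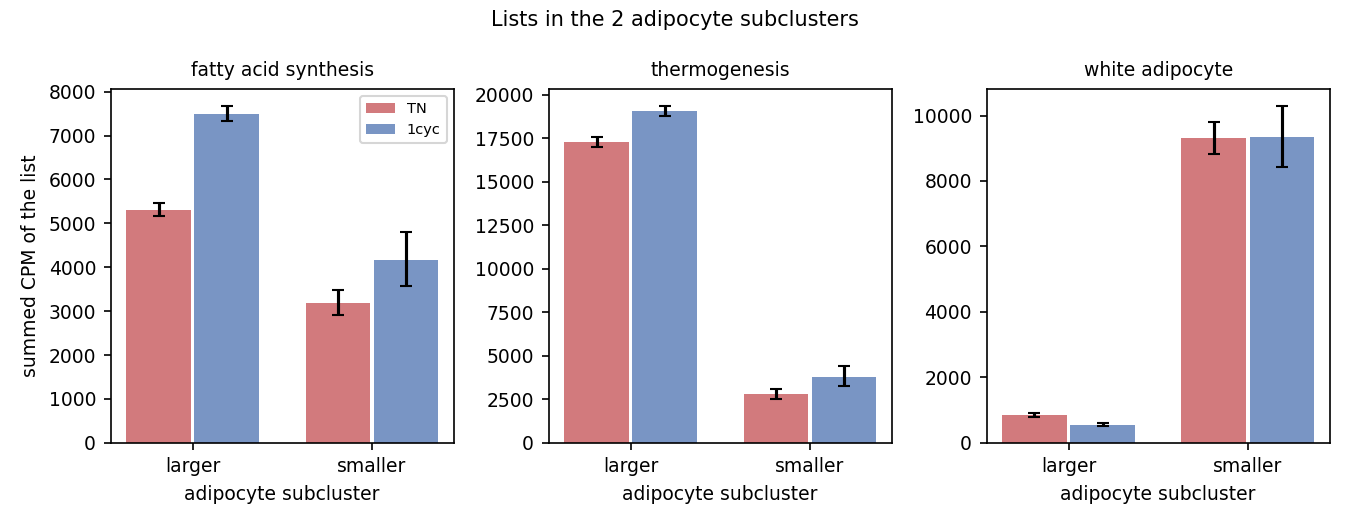
Summed CPM of the fatty acid synthesis, thermogenesis and white adipocyte lists in the larger and smaller adipocyte subclusters of the TN and 1cyc libraries, with 95% Poisson intervals for counting error, in the clustering without the fatty acid synthesis list alone. The white adipocyte list, whose genes helped define these subclusters, is at 9310 CPM and 9334 CPM in the smaller subcluster and at 835 CPM and 546 CPM in the larger one.

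Insulin signalling genes went both ways, with 6 of 14 higher, 8 lower and a median log2 ratio of −0.09 (−0.25 to 0.06, percentile 15.9). In the smaller subcluster the median was −0.41 (−0.81 to −0.06, percentile 1.73), below the middle 95% of random lists, with 4 of 6 lower. But the summed ratio there was 0.899 (0.771 to 1.05), which includes 1, and rested on 30 1cyc nuclei. Over all adipocyte nuclei Pik3r1 had a ratio of 0.699 (0.612 to 0.798) and the insulin receptor gene Insr 0.809 (0.708 to 0.924), while Mtor had 1.57 (1.28 to 1.93) and Akt2 1.39 (1.11 to 1.74). There nuclear-encoded electron transport genes had a median of 0.11 (−0.02 to 0.26, percentile 80.7) with 8 of 12 higher. Circadian clock genes had 0.14 (−0.01 to 0.28, percentile 82.3) with 5 of 7 higher, and extracellular matrix genes −0.16 (−0.29 to 0.17, percentile 14.1) with 2 of 3 lower. The 3 measured vascular growth factors had a median of 0.01 (−0.09 to 0.11, percentile 41.5), which turned below 0 with each of the other 3 scalings of the sums; Vegfa had a ratio of 1.71 (1.58 to 1.86) and Angpt1 0.763 (0.701 to 0.830). Lists with under 3 measured members were summed. Cholesterol synthesis genes had 319 CPM in TN and 527 CPM in 1cyc (ratio 1.65, 1.44 to 1.91), and immediate early and heat shock genes 184 CPM and 308 CPM (ratio 1.68, 1.39 to 2.03). Cell cycle genes had 88.4 CPM and 120 CPM (ratio 1.35, 1.02 to 1.80), and type I interferon response genes 130 CPM and 135 CPM (ratio 1.04, 0.811 to 1.33).

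Markers of other cells and of RNA quality also differed within adipocyte nuclei. Adipocyte markers had a median log2 ratio of 0.34 (0.22 to 0.38), with 13 of 16 higher in 1cyc. Several of these markers are also on the thermogenesis and synthesis lists. Fibroblast or progenitor markers had a median log2 ratio of −1.31 (−1.68 to −0.79, percentile 0.03), further below 0 than the white adipocyte list, with 0 of 3 measured members higher and 2 at least 2-fold lower. Their summed ratio was 0.548 (0.460 to 0.652). Clustered without the fatty acid synthesis list, they stood at 1178 CPM in the smaller TN subcluster and 241 CPM in the larger. The lower share of the smaller subcluster in 1cyc can therefore give part of this difference. Within the smaller subcluster the ratio was 0.614 (0.405 to 0.902), and within the larger 0.765 (0.621 to 0.941). Blood genes stood at 403 CPM and 254 CPM (ratio 0.630, 0.536 to 0.740). Pericyte markers stood at 197 CPM and 71.9 CPM (ratio 0.364, 0.273 to 0.481), but Steap4 held 144 of their 203 TN and 26 of their 69 1cyc UMIs, and Cspg4 had a ratio of 1.11 (0.643 to 1.91). Endothelial markers had a ratio of 0.810 (0.667 to 0.983), but Mecom held 123 of their 250 TN and 81 of their 189 1cyc UMIs with 0.706 (0.526 to 0.942), and Cdh13 had 1.21 (0.801 to 1.83). Macrophage or monocyte markers had 0.815 (0.651 to 1.02), with 0.698 (0.489 to 0.989) for Mertk and 0.951 (0.667 to 1.35) for Rbpj. Schwann cell markers had 0.797 (0.658 to 0.963), with 0.531 (0.373 to 0.747) for Scn7a and 1.04 (0.753 to 1.45) for Mbp. Mast cell markers had 1.46 (1.11 to 1.93), of which Kit held 92 of 93 TN and 122 of 127 1cyc UMIs. B lymphocyte markers had 2.07 (1.05 to 4.27) on 14 and 27 UMIs. The intervals for lymphatic endothelial, smooth muscle, dendritic cell, T or NK lymphocyte, neutrophil, skeletal muscle, mesothelial and epithelial markers included 1. Sex-linked genes had a median log2 ratio of −0.06 (−0.29 to 0.18) with 2 of 4 measured members higher, but a summed ratio of 0.878 (0.793 to 0.971). Mitochondrially encoded genes had a median log2 ratio of −0.34 (−0.39 to −0.29), with 11 of 12 lower in the 1cyc nuclei kept by the filter.

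Nuclei with many fatty acid synthesis transcripts were more frequent in 1cyc. After thinning to 500 UMIs, 66 of 1023 TN adipocyte nuclei (6.45%, 5.02 to 8.14) and 140 of 759 1cyc nuclei (18.4%, 15.7 to 21.4) held more than 5 UMIs of the list. The thinning left out 166 1cyc nuclei and 0 TN nuclei, and without thinning the shares were 36.2% and 54.8%. Over 20 thinnings the shares ranged from 4.59% to 6.65% in TN and from 18.4% to 22.8% in 1cyc. The limit divides a range and not a cell type, with 90 TN and 88 1cyc nuclei at exactly 5 UMIs. A Poisson distribution with each library's mean, 2.55 UMIs in TN and 3.67 UMIs in 1cyc, puts 4.57% and 16.6% of nuclei above the limit. The variance over the mean was 1.22 in TN and 1.51 in 1cyc, where the middle 95% of matched random lists ended at 1.51 and 1.53. Of non-adipocyte nuclei, 0 of 270 in TN and 1 of 111 in 1cyc (0.901%) passed the limit, at median depths of 1261 UMIs and 973 UMIs against 837 UMIs and 897 UMIs in adipocytes.

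Across adipocyte nuclei, the correlation between alternate genes of the fatty acid synthesis list was 0.0543 in TN (percentile 91.5 of random lists) and 0.111 in 1cyc (percentile 97.6), where the middle 95% of random lists ended at 0.0825 and 0.107. The median of 20 thinnings, added after these values were seen, was 0.0182 in TN (percentile 76.6) and 0.182 in 1cyc (percentile 98.7). Over all alternative settings the value ranged from −0.0144 to 0.209 in TN and from 0.0562 to 0.343 in 1cyc. Apart from the 20 thinnings, no random lists were drawn for these settings. Thermogenesis UMIs averaged 10.9 in 1cyc nuclei above the limit and 9.46 in the rest, and 8.20 and 8.03 in TN, with medians of 10 and 9 in 1cyc and 8 and 8 in TN.

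**Figure D4:**
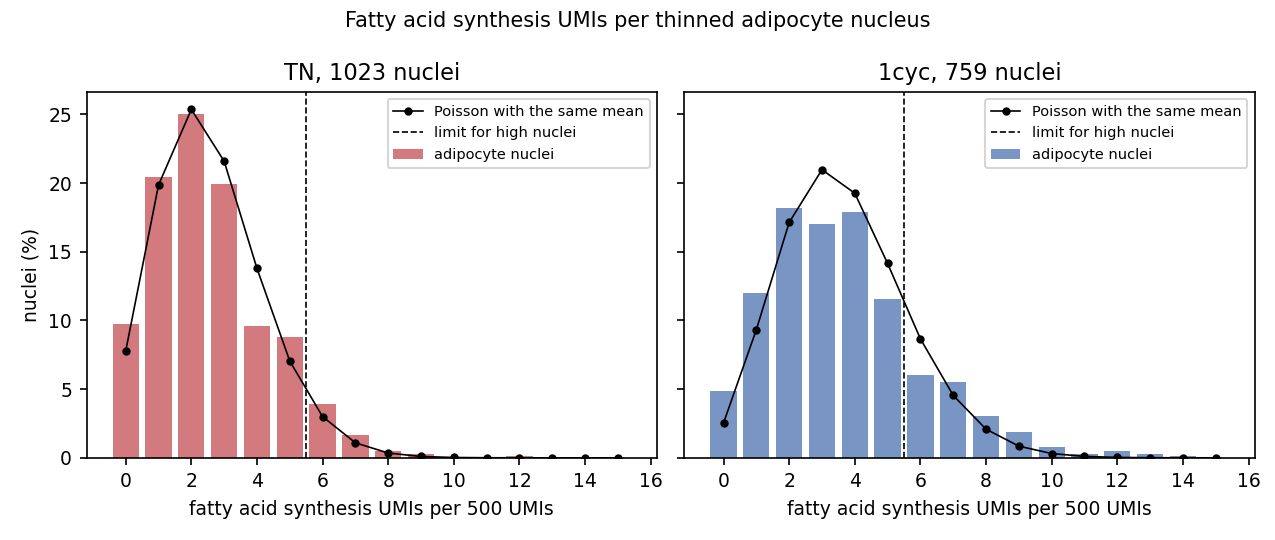
Share of adipocyte nuclei (%) by number of fatty acid synthesis UMIs after thinning to 500 UMIs, for 1023 TN and 759 1cyc nuclei. Black points are a Poisson distribution with the same mean and the dashed line the limit, above which lie 6.45% of TN and 18.4% of 1cyc nuclei.

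No other class reached 100 nuclei in both libraries after filtering, and the largest, fibroblasts or progenitors, had 136 in TN and 74 in 1cyc. With no filter on nuclei, a choice made after seeing this, that class had 294 TN and 129 1cyc nuclei. Among 1686 genes, 20 were at least 2-fold higher and 39 at least 2-fold lower in 1cyc. Kpna1, an importin gene, had a ratio of 2.80 (2.05 to 3.81) and Camk1d 1.82 (1.46 to 2.26). Col5a3, a collagen gene, stood at 398 CPM in TN and 795 CPM in 1cyc (interval of the ratio 1.51 to 2.63). The complement gene C7 had 0.295 (0.192 to 0.435), Csmd1 0.222 (0.0991 to 0.435) and Mmp3, a matrix metalloproteinase gene, 0.124 (0.0146 to 0.471).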

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

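The 20% limit used here was chosen after the libraries' mitochondrial shares were seen. In the 1cyc library, 2275 of 4321 deposited barcodes (52.6%, 51.1 to 54.1) held at least 20% mitochondrially encoded UMIs, against 84 of 2551 (3.29%, 2.63 to 4.06) in TN. The comparisons of filtered nuclei did not use these barcodes, which entered only the values given with no filter or over all deposited barcodes. The share stands out because it lies far above that of the control library. But the lowest deposited barcode held 500 UMIs in TN and 262 in 1cyc. The barcodes above the 20% limit held a median of 328 UMIs in 1cyc and 716 UMIs in TN. Most of the 1cyc ones thus lay below the lowest TN barcode, where TN could hold no counterpart. The shares, and the levels that follow, therefore come from unlike ranges of depth. Per 1e6 UMIs of genes not encoded in mitochondria, fatty acid synthesis transcripts stood at 6508 (6305 to 6717) in these 1cyc barcodes and 2157 (1813 to 2547) in these TN barcodes. Thermogenesis transcripts stood at 16221 and 5556, blood transcripts at 25117 and 16714, and white adipocyte transcripts at 910.0 and 652.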

How the results depend on the processing

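The settings with a 10% mitochondrial limit, the larger subcluster only, the median of 20 thinnings and unnamed clusters counted were chosen after seeing the data. The last counts as adipocyte an unnamed cluster that scored best as one, with no filter on nuclei, at the 2% mitochondrial limit and at resolution 1.2. No paired analysis was possible because each condition is 1 library. All 405 alternative values of the 24 named genes kept their sign and 397 were still at least 2-fold apart; a gene under the UMI minimum in a setting has no value there, and of the 42 lower genes 16 were measured in the larger subcluster. The fatty acid synthesis list ranged from 0.32 to 0.84, with 0.84 at the 2% mitochondrial limit, 0.77 there with the unnamed cluster counted, and 0.72 with scaling within library. The thermogenesis list was at 0.68 with the 2% limit, 0.55 there with the unnamed cluster counted, 0.28 with TMM and 0.29 in the larger subcluster. TMM moved the median of all genes from 0.03 to −0.08, so that every log2 ratio under it is lower by that shift. Of 219 values of 12 other lists, 197 kept their sign, and lipolysis reversed to −0.0204 at the 2% limit. Extracellular matrix ranged from −0.27 to 0.40, circadian clock from −0.17 to 0.25 and vascular growth factors from −0.39 to 0.12. Insulin signalling ranged from −0.34 to 0.02 and nuclear-encoded electron transport from −0.01 to 0.49. The main intervals of these lists included 0. With no filter on nuclei and the unnamed cluster counted, mitochondrially encoded genes reversed to 1.56, fatty acid synthesis was at 0.32 and thermogenesis at 0.14, and lipolysis reversed to −0.000711 and glycogen metabolism to −0.00898. The totals in that setting include mitochondrially encoded UMIs, which were 5.74% of all deposited UMIs in TN and 14.2% in 1cyc. A larger share of them lowers the CPM of all other genes in 1cyc, so these 2 reversals near 0 may reflect the scaling alone. There fatty acid uptake and triglyceride synthesis was at 0.09, its lowest, and fatty acid oxidation at 0.07, its lowest; at the 2% limit these were 0.16 and 0.64, glycolysis was 0.80, and with TMM oxidation was 0.12. Uptake was 0.22 with at least 400 UMIs per gene. The causes were not tested.

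Genes at least 2-fold higher numbered 54 with no filter on nuclei, 76 there with the unnamed cluster counted, 54 with the 10% limit, 57 with scaling within library, 21 with TMM and 19 with thinned nuclei; with thinned nuclei 10 were lower, and in the larger subcluster 7 were lower. With no filter on genes, 3531 were higher and 2278 lower, most of them on few UMIs, and with at least 400 UMIs 5 and 7, as fewer genes were tested. The adipocyte share in TN and 1cyc was 68.6% and 31.0% with no filter on nuclei, 57.9% and 57.0% at the 2% limit, 72.2% and 80% at the 10% limit, and 62.8% and 83.5% at resolution 1.2. With the unnamed cluster counted it was 70.2% and 92.6% with no filter, 83.4% and 92.8% at the 2% limit and 77.4% and 86.8% at resolution 1.2. That cluster held 14.6% of TN and 3.31% of 1cyc nuclei at resolution 1.2, and with no filter, where mitochondrially encoded genes led it, 1.61% and 61.6%. Nuclei high in fatty acid synthesis UMIs were 24.8% and 48.0% at the 75th percentile and 2.54% and 12.4% at the 95th. The TN share was 8.90% when thinned to 300 UMIs, and the 1cyc share was 24.1% when thinned to 1000 UMIs, 33.9% at the 2% limit and 14.3% with no filter and the unnamed cluster counted. Co-variation in 1cyc was 0.218 at the 2% limit, 0.243 with doublet calls kept, 0.0729 at 300 UMIs and 0.0562 between the first and second part of the list. In TN it was 0.0847 with at least 400 detected genes, −0.0144 with doublet calls kept and 0.0785 at the 2% limit with the unnamed cluster counted. At 1000 UMIs it was 0.209 in TN and 0.343 in 1cyc. The causes of these moves were not tested.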

Other observations

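The tests of free RNA, of the smaller subcluster and of white fat described here were chosen after the results they bear on were seen; those of gene length and of the time of day were written before. Within the larger subcluster of the clustering without the fatty acid synthesis list, the genes at least 2-fold higher in 1cyc included some outside the named ones. Lipa, the lysosomal acid lipase gene, had a CPM ratio of 2.07 (1.42 to 3.06), Crat, the carnitine acetyltransferase gene, 2.06 (1.54 to 2.77), G0s2, which encodes an inhibitor of lipolysis, 2.09 (1.44 to 3.07) and Ucp3, a mitochondrial carrier gene, 2.32 (1.55 to 3.54). Among the 7 genes at least 2-fold lower there, Svep1, an extracellular matrix gene, had 0.458 (0.391 to 0.535) and the engulfment adaptor gene Gulp1 0.332 (0.246 to 0.444). These genes were picked after their values were seen.

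The fatty acid synthesis list was higher in 1cyc adipocyte nuclei. Free RNA in that library would raise it in all nuclei. In non-adipocyte nuclei the list differed by 787 CPM (556 to 1023) and in adipocyte nuclei by 2353 CPM (2134 to 2572). Free RNA thus does not account for the whole if both kinds of nuclei carry the same amount of it. That amount was not measured, and RNA attached to adipocyte nuclei alone would not show in this comparison. Shorter genes did tend to be higher in 1cyc, with a rank correlation of −0.204 between gene length and log2 ratio. The list still lay at the 100th percentile of random lists matched on level and gene length. That argues against this shift as the source of the list's difference. The other lists and the named genes were not matched on length. Fewer nuclei of the smaller subcluster could raise the list, yet within the larger subcluster its median log2 ratio was 0.56 (0.44 to 0.70) against 0.61 in all adipocyte nuclei. The response to cold, the hypothesis the design names, and any other difference between the libraries stay open, since each condition is 1 library.

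The white adipocyte list was lower in 1cyc adipocyte nuclei, and the 1cyc library held fewer nuclei of the smaller subcluster, which is rich in it. Clustered without the list's own genes, that subcluster held 13.4% of TN and 4.39% of 1cyc adipocyte UMIs. These shares also depend on the depth of its nuclei, a median of 1450 UMIs in TN and 1190 in 1cyc. TN levels with the 1cyc shares of UMIs give 68.1% of the difference. The lower share of that subcluster is thus a candidate explanation for part of the difference. Whether it is the whole cause stays open. The list's ratio was also 0.640 (0.573 to 0.714) within the larger subcluster and 0.794 (0.702 to 0.898) there without Nnat. But Slc7a10, which leads the smaller subcluster, held 21 TN and 2 1cyc UMIs in the larger one (ratio 0.0924, 0.0105 to 0.378), so nuclei of the smaller kind may have been left there in TN. A first version of this test used a clustering that included the list's genes, which define the smaller subcluster (1.00, 0.895 to 1.12 within it), and was replaced; there Slc7a10 held 4 TN and 0 1cyc UMIs in the larger subcluster, where the list's ratio without Nnat was 0.822 (0.725 to 0.933). White fat collected with the TN tissue may have added nuclei of the smaller kind. Their TN thermogenesis transcripts stood at 2802 CPM (2543 to 3081) in the first clustering and 2847 CPM (2572 to 3143) in the one that replaced it. TN non-adipocyte nuclei had 2935 CPM (2780 to 3096), but resident adipocytes of low thermogenic activity predict the same value. Hoxc8, Hoxc9, Hoxc10, Tcf21 and Mest of the white list held 0 UMIs in the TN smaller subcluster in both clusterings. Their level in white fat was not measured here, so these values cannot decide.

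Arntl was higher and Per2 lower in 1cyc adipocyte nuclei, Arntl on 1 and 14 UMIs, and over all deposited barcodes Arntl had 10 UMIs in TN and 31 in 1cyc (ratio 3.45, 1.65 to 7.88) and Per2 134 and 74 (ratio 0.614, 0.456 to 0.821). Npas2, which peaks with Arntl, went the other way there with 22 and 8 UMIs (ratio 0.404, 0.156 to 0.943), and Cry1 had 1.11 (0.654 to 1.89) and Clock 0.993 (0.837 to 1.18). Another time of day at collection could give the Arntl and Per2 difference and would lower clock output genes that peak opposite to Arntl, but the ratio of Nr1d1, Dbp, Per3, Ciart and Tef together was 1.18 (1.07 to 1.31). The bound set before this value was seen, a lower limit above 1 as an argument against another time of day, was met. But the value rests mainly on Tef, which held 648 of the 778 TN UMIs, while Per3 held 0. Without Tef the ratio was 1.11 (0.865 to 1.43), which includes 1. The deposited barcodes also differed in make-up, with 5.74% of all UMIs mitochondrially encoded in TN and 14.2% in 1cyc. The test therefore cannot decide, and another time of day stays open. The response to cold and other differences between the libraries also stay open, as untested.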
